A study of Homo sapiens with 12 samples.

How the data were processed

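H3K27ac, the acetylated lysine on histone H3 that marks active promoters and enhancers, was mapped by ChIP-seq in SUDHL4, a diffuse large B-cell lymphoma line of germinal-centre B-cell type. Per the labels, single clones were made with CRISPR/Cas9 and kept as stable lines: 2 control clones edited at PPP1R12C and wild type for both acetyltransferase genes (WT), 2 clones without CREBBP (guides against exons 15 and 20) and 2 without EP300 (guides against exons 17 and 24). The name of the first CREBBP-KO clone carries another exon number than its protocol, which names exon 15. The series has 12 samples, of which 6 are immunoprecipitated libraries and 6 are their inputs. Each immunoprecipitated library has its own peak list, and the inputs entered only through those lists. Replicate numbers only name clones and pair nothing across genotypes.

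Per the labels' protocols, chromatin was fixed with 1% formaldehyde, sonicated to fragments of 200 to 500 bp and sequenced as paired-end reads of 150 bp, with only an average read number over all samples given. Per the submitters' processing notes, the tools were CASAVA 1.8, Bowtie2 2.1.0 and SAMtools 0.1.19 with the genome build hg19. Per the file headers, each list sets a library against its own input, so peaks were called per clone and not on pooled samples. The peak caller is not given in the sources used here. The deposited start and end of each peak are genome positions, and the deposited score per peak runs from 14 or 15 to 170 with no stated meaning. That score is the authors' own value and was used only to rank peaks within 1 list and, as a mean over the WT clones, to form the classes of the shuffled lists. The depth of each library is unknown, so no interval here covers sequencing depth. Starts were read as counted from 0, which the files do not state, so a printed start carries an uncertainty of 1 base.

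Peaks of the 6 lists that shared a base were joined into 48876 merged regions, and a clone had a region if at least 1 base of it was covered. A region was lost in a knock-out if both WT clones and neither knock-out clone had it, and gained in the reverse case. The same 4 clones were also crossed, with 1 clone of each genotype on either side, to give counts from regions on which clones of 1 genotype disagree. Any trait shared by both clones of a genotype, such as ChIP yield, keeps these counts low. A count above them therefore shows agreement of the 2 clones and does not single out the genotype as its source. Overlap of lists was measured as the Jaccard index (bedtools 2.31.1). The overlap of the lost regions was set against independent lists, against simulated unchanged clones and, added after the overlap was seen, against lists shuffled within classes of WT score and covered length. A split with 1 WT clone as the control of each knock-out was also run and is not used, because it leaves the shared count unchanged by construction. Wide domains were peaks stitched across gaps of up to 12.5 kb that together covered at least 10 kb. With 2 clones against 2, an exact permutation test cannot go below p = 0.333.

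Covered length was compared with limma 3.58.1 (R 4.3.3) on log2(covered bases + 100), centred on the clone median over features covered in all 6 clones. Features with at least 500 bases in at least 2 clones entered, all 6 clones shared 1 estimate of the spread, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. Log2 differences on this scale understate changes of short regions. Where a group has no covered bases, the size of the log2 difference depends on the pseudocount, and the SE does not cover that choice. The test had been planned per gene, but the annotation at hand is of another genome build (GRCh38), so it ran on merged regions, as the design provided. For the same reason the promoter shares, the promoter and distal split, the tests of the fixed gene lists and of cell type markers as gene sets, and the alternatives that need transcription start sites were not run.

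The fit on windows of 1 Mb (at least 2000 covered bases in at least 2 clones), the tests of regions lost per window and the split by covered length were added after the region counts were seen. The window fit was first run with the centring taken over only the windows past that filter, and then with the centring that the region fit uses. The second is reported because it follows the planned rule, a choice made with both outcomes known, and the first, which called 7 windows in CREBBP-KO where the second called 0, stands among the alternatives. To name windows, 25 of them were used that had been picked as holding an edited gene or a member of the fixed gene lists. They were picked after the format of the files was examined and before any comparison was computed. The positions of these genes on hg19 are general knowledge and come from no file used here, except that their chromosomes were checked against the GRCh38 gene table. Each window holds other genes too, so its value belongs to the window and not to the gene that names it. A list is represented by 1 to 5 windows of its many genes, which does not replace the planned tests of the full lists. Some windows of the original pick are not reported here and were left out of every count, median and adjustment over the list after their values were known. This moved 1 call, that of CD83 in CREBBP-KO without the first CREBBP-KO clone, to just under the threshold over the list alone.

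On data simulated for EP300-KO against WT with 200 changed features, the fit on 19860 regions recovered 24% of changes of 1 and 58% of changes of 2 on the log2 scale, with 9 false calls among 91. On 1971 windows it recovered 82% and 98%, with 7 false calls among 187. The simulation shuffled the spread between clones over features, which removed its link to covered length. It also changed fewer features than were called in EP300-KO against WT (1458 regions and 274 windows). These rates therefore need not hold for the measured data. Regions were named by rules fixed before the data were examined: the largest changes past the threshold in each direction, or, where fewer than 10 passed, those whose clones did not overlap, and the widest regions of each set. The text names the first few of each. Alternatives changed the peak threshold, the overlap rule, the joining of peaks, the pseudocount, the centring, the filter, the clones in the fit and the window grid, and left out each clone in turn. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.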

Results

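H3K27ac peak lists were obtained for 6 single clones of the lymphoma line SUDHL4, 2 for each of 3 genotypes. CREBBP and EP300 are paralogous histone acetyltransferases, and the comparisons ask how the acetylation landscape differs when either is absent. The WT clones had 46940 and 40658 peaks, the CREBBP-KO clones 36096 and 41099, and the EP300-KO clones 35054 and 35841. Covered length was 32.6 ± 1.83 Mb (mean ± SD, n = 2) in WT, 31.7 ± 4.86 Mb in CREBBP-KO and 26.1 ± 0.104 Mb in EP300-KO. Median peak width was 442 ± 21.9, 478 ± 18.4 and 457 ± 5.66 bases in the same order. Both EP300-KO clones lay below both WT clones in peak number and in covered length, which gives an exact two-sided permutation p of 0.333, the smallest that 2 clones against 2 allow. In CREBBP-KO the covered length of the clones spanned that of the WT clones. The clones came from separate single cells, so the tests measure the spread between clones.

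The EP300-KO clones shared more acetylated sequence with each other than with any other clone, whereas WT and CREBBP-KO clones did not separate. The second WT clone overlapped both CREBBP-KO clones (0.764 and 0.782) more than the first WT clone (0.732), and each CREBBP-KO clone overlapped it more than the other CREBBP-KO clone (0.758). The Jaccard index averaged 0.765 over the 3 pairs of the same genotype and 0.694 over the 12 other pairs. It was highest between the EP300-KO clones (0.806) and lowest between the first WT clone and the first EP300-KO clone (0.627). Among the 15 ways to pair the 6 clones, only the real one gave a difference this large (0.0713, one-sided exact permutation p = 0.0667, the smallest possible). Of the 48876 merged regions, 21911 had a peak in all 6 clones. The first WT clone alone held 5236 regions and the second CREBBP-KO clone alone held 2968.

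Loss of CREBBP was compared with WT first. No window of 1 Mb and few single regions changed past the threshold in these clones. In limma's fit over 19860 regions, 2 fell and none rose. One lay on chromosome 5 at 180687558 to 180689185 (hg19), with 1609 ± 26.9 covered bases in WT and none in CREBBP-KO (log2 difference -4.06, SE 0.16, adjusted p = 0.015). The other lay on chromosome X at 24497215 to 24498876, with 1475 ± 185 covered bases in WT and none in CREBBP-KO (log2 difference -3.93, SE 0.18, adjusted p = 0.016). Before adjustment, 1753 regions and 354 of 1971 windows had p under 0.05. Both calls ended with only the 4 clones compared and without the first WT clone, the first CREBBP-KO clone or either EP300-KO clone (adjusted p from 0.147 to 0.21), while 9 regions and 3 windows passed without the second CREBBP-KO clone and 211 regions and 213 windows without the second WT clone, of which 27 regions and 77 windows were lower in CREBBP-KO and the rest higher. At equal list length 8 regions were higher and 6 lower, so the balance of falls and rises did not hold. With no centring 41 windows passed, with the centring over filtered windows 7, and without the first WT clone 2.

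The CD83 and HLA-DRA windows had the largest differences among the named windows in CREBBP-KO. The CD83 window (chromosome 6, 14 to 15 Mb), named for an activation marker of light zone B cells, had 6.55 ± 1.46 kb covered in WT and 1.69 ± 0.699 kb in CREBBP-KO (n = 2 each). Its log2 difference was -1.86 (SE 0.26), with limma's adjusted p at 0.053 over all windows and 0.0051 adjusted over the list alone. The HLA-DRA window (chromosome 6, 32 to 33 Mb), named for an MHC class II chain, had 28.5 ± 0.288 kb in WT and 20.2 ± 5.50 kb in CREBBP-KO. Its log2 difference was -0.44 (SE 0.10), with adjusted p = 0.15 over all windows and 0.033 adjusted over the list alone. Of the 24 named windows tested, 0 passed in limma over all windows and 2, these, when adjusted over the list alone. The other members of their lists differed less, CD74 by -0.16 (adjusted p = 0.38) and MYC by -0.06 (adjusted p = 0.74), as against -0.25 for IRF8, -0.23 for IRF4 and -0.20 for the control ACTB, none of which passed. Without the first CREBBP-KO clone CD83 lay close to the threshold over the list alone (0.049) and HLA-DRA missed it (0.16), HLA-DRA also missed it without either WT clone (0.053 for each) or either EP300-KO clone (0.054 for each), and so it did with no centring (0.072) and with the 4 clones alone (0.075). CD83 passed over all windows in 4 of 12 alternatives: without the second WT clone (0.014), with no centring (9.64e-09), with a pseudocount of 1000 (0.044) and with the centring over filtered windows (0.045). The window of the edited gene CREBBP had a log2 difference of 0.02 (SE 0.07), and those of EP300 and PPP1R12C had 0.04 and 0.07. A window of this size does not test whether a gene was disrupted.

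By presence and absence of peaks, 1491 regions were lost and 609 were gained in CREBBP-KO. The crossed counts of the same 4 clones ranged from 86 to 1903, so neither number exceeded the highest of them. With lists limited to the same 35054 best-scoring peaks, 888 were lost and 1137 gained, which turned the balance around, and both numbers then exceeded the highest crossed count of 789. The lowest score kept was 33 and 29 in the WT clones and 24 and 30 in the CREBBP-KO clones. A peak cut from a list counts as absent, so a region gained at equal length need not hold a new peak. Of the regions that scored in the upper 50% of both WT lists, 23 had no peak in either CREBBP-KO clone and 3 were gained by the same rule, against at most 1 in the crossed counts. The share lost was raised above the genome-wide 4.94% in 6 of 1089 windows (exact binomial tests, Benjamini-Hochberg adjusted), which held few of the lost regions. The first was chromosome 11 at 14 to 15 Mb, where 9 of 14 regions were lost (64.3%, Wilson 95% interval 38.8 to 83.7%, adjusted p = 3.03e-06). These tests take 1 loss rate for all regions, although short regions were lost more often. Neighbouring regions are not independent, and the crossed counts reached at most 1 such window.

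Loss of EP300 went with a broad reduction of H3K27ac peaks in both clones. Against WT, 4471 regions were lost and 850 gained, while the crossed counts reached at most 542. In limma's fit 1217 regions fell and 241 rose. The region that fell most lay on chromosome 4 at 26827573 to 26834401, with 5430.5 ± 1822 covered bases in WT and none in EP300-KO (log2 difference -5.55, SE 0.29, adjusted p = 0.0032). Next came chromosome 9 at 114794927 to 114798507, with 3366.5 ± 148 bases in WT and none in EP300-KO (-4.91, SE 0.18, adjusted p = 0.0012), and chromosome 11 at 72857492 to 72861002, with 3037.5 ± 401 bases in WT and none (-4.76, SE 0.12, adjusted p = 0.0008). The largest rises were on chromosome 3 at 149751144 to 149755220 (none in WT and 3545.5 ± 752 bases in EP300-KO, 5.37, SE 0.90, adjusted p = 0.031) and on chromosome 7 at 29327788 to 29331131 (none and 2636.5 ± 1001 bases, 4.93, SE 0.47, adjusted p = 0.009). The chromosome 3 call ended without any of the 4 clones compared (adjusted p from 0.059 to 0.0996) and the chromosome 7 call without either EP300-KO clone (0.2 and 0.077). The next, on chromosome 18 at 6254491 to 6257034 had no peak in WT and 2475.5 ± 78.5 bases in EP300-KO (4.89, SE 0.25, adjusted p = 0.0031). That region also had 1323.5 ± 315 bases in CREBBP-KO, where it did not pass (adjusted p = 0.056). The total of 1458 called regions was 670 without the first WT clone (490 lower, 180 higher), 953 without the second (540 lower, 413 higher) and 861 without the first EP300-KO clone (843 lower, 18 higher). Without the second EP300-KO clone 1463 were lower and 61 higher, and without centring 1471 and 108. At equal list length 2262 regions were lost and 1517 gained, against crossed counts of at most 350. Peaks cut from the WT lists count as absent here too, so these gains need not be new peaks.

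**Figure D1:**
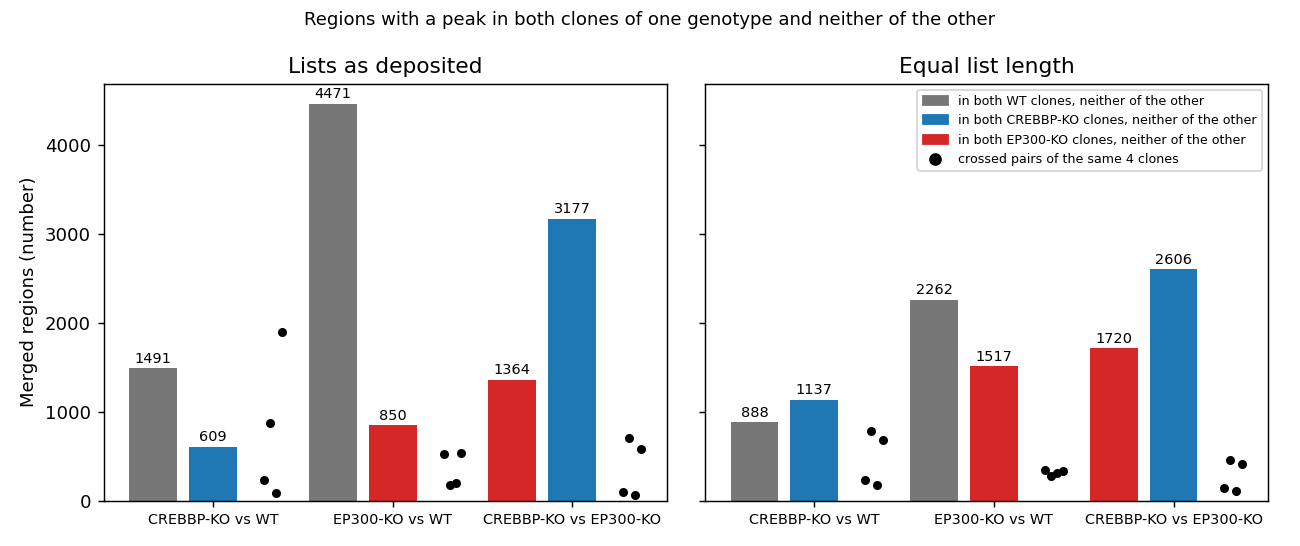
The y axis gives the number of merged regions with a peak in both clones of one genotype and neither clone of the other, for the lists as deposited (left) and limited to equal length (right). Bars are coloured by the genotype that has the peaks, and black points are the 4 crossed counts of the same clones. The 4471 regions lost in EP300-KO stand above crossed counts of at most 542, whereas the 1491 lost in CREBBP-KO lie under the highest crossed count of 1903. At equal length (right) the CREBBP-KO counts of 888 lost and 1137 gained also stand above their crossed counts of at most 789. On that side a peak cut from a list counts as absent.

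Lost regions were short, and so were gained ones. Median covered length was 273 bases for lost and 246 for gained regions in EP300-KO. In CREBBP-KO it was 218.5 and 217, against 835.5 for regions in all 6 clones. Shortness is therefore not particular to losses. The share of WT regions lost in EP300-KO was 45.6% (Wilson 95% interval 44.1 to 47.1%) among those with under 250 covered bases in WT, 1772 of 7688 from 250 to 500, 7.56% from 500 to 1000, 133 of 6326 from 1000 to 2000 and 0.298% over 2000. The same classes lost 21.3%, 6.37%, 1.07%, 0.174% and 0 of 3694 regions in CREBBP-KO, the last with a Wilson upper bound of 0.104%. These intervals treat regions as independent. Regions that scored in the upper 50% of both WT lists were lost too, 198 of 17057 in EP300-KO, against at most 2 in the crossed counts. The reverse count was 55.

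**Figure D2:**
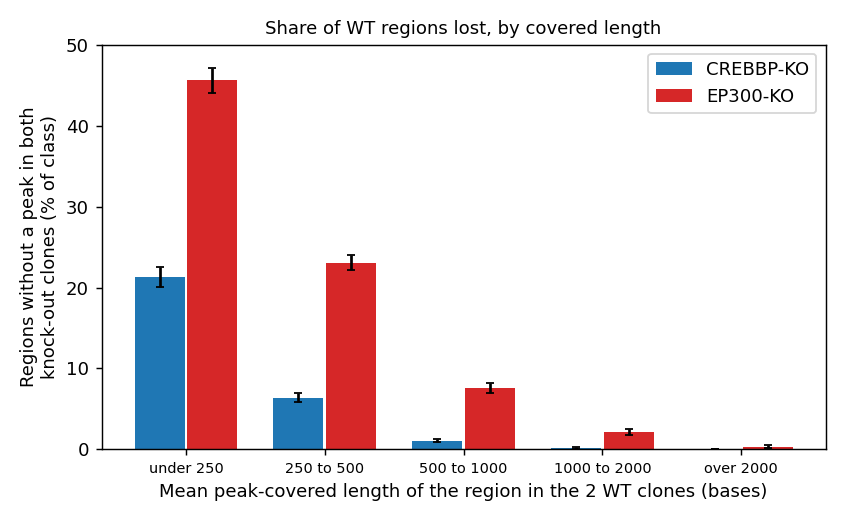
The y axis gives the percentage of regions shared by both WT clones that had no peak in either clone of a knock-out, by mean covered length in WT (x axis, bases), with Wilson 95% intervals. The share falls from 45.6% to 0.298% in EP300-KO and from 21.3% to 0 in CREBBP-KO.

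Wide acetylated domains were fewer in EP300-KO. Promoters were not set apart, so these domains cannot be taken as clustered enhancers. There were 497 ± 32.5 in WT, 508 ± 139 in CREBBP-KO and 279.5 ± 16.3 in EP300-KO (n = 2 each, exact permutation p = 0.333 for EP300-KO against WT). Present in both WT clones and neither EP300-KO clone were 141 domains, the reverse held for 1, and crossed counts reached at most 5. Absence means only that no stitched stretch there reached 10 kb covered, so peaks can remain. The domain on chromosome 13 at 30866224 to 30951647 still held 15.5 ± 0.497 kb in EP300-KO, against 27.4 ± 0.63 kb in WT. That on chromosome 12 at 25145275 to 25179843 held 10.5 ± 3.46 kb in EP300-KO, against 22.6 ± 2.03 kb in WT. The domain with the largest difference spanned 73.9 kb on chromosome 5 at 10561970 to 10635891. It held 20.5 ± 0.351 kb of peaks in WT, 18.5 ± 4.29 kb in CREBBP-KO and 2.44 ± 0.503 kb in EP300-KO. A second, on chromosome 1 at 42087364 to 42150157, held 23.1 ± 3.37 kb in WT, 24.3 ± 2.36 kb in CREBBP-KO and 7.03 ± 1.12 kb in EP300-KO. In CREBBP-KO against WT, 7 domains were lost and 21 gained, with crossed counts of up to 39.

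**Figure D3:**
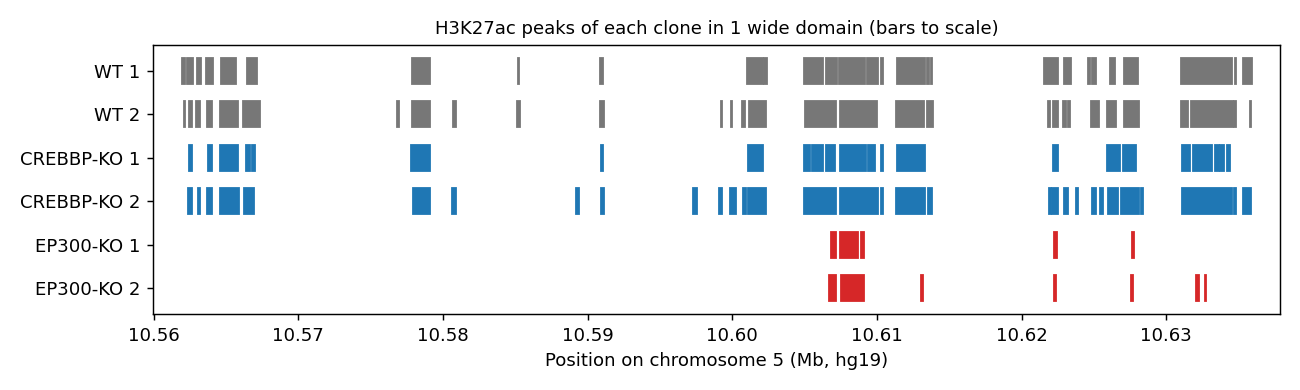
Each bar is a peak, drawn to scale along chromosome 5 (x axis, Mb, hg19), with a line of peaks per clone. The WT and CREBBP-KO clones have 23 to 31 peaks across the domain, and the EP300-KO clones have 5 and 7.

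Windows named for the germinal-centre dark zone, where germinal-centre B cells divide, had less acetylated sequence in EP300-KO, in 2 of 3 cases past the threshold. The FOXO1 window (chromosome 13, 41 to 42 Mb), named for a transcription factor of dark zone cells, fell from 105 ± 3.05 kb in WT to 64.3 ± 3.50 kb in EP300-KO (limma log2 difference -0.45, SE 0.06, adjusted p = 0.0091). The CXCR4 window (chromosome 2), named for the receptor that holds cells in that zone, fell from 36.1 ± 0.891 to 22.9 ± 1.96 kb (-0.40, SE 0.09, adjusted p = 0.039). The S1PR2 window differed by -0.08 (SE 0.05) and did not pass (adjusted p = 0.28). The median log2 difference of the 3 windows, -0.40, lay at percentile 0.35 of 10000 random sets of windows matched on covered length. The light zone windows, CD83 and MYC, lay at percentile 1.14 in EP300-KO (median -0.70) and 0 in CREBBP-KO (median -0.96), and the MHC class II windows, HLA-DRA and CD74, at 0.66 in CREBBP-KO (median -0.30). With 2 windows a list's median is their mean, and in the light zone CD83 alone carried it, since MYC differed by -0.12 in EP300-KO and -0.06 in CREBBP-KO. For the direct comparison of the knock-outs the dark zone lay at percentile 100. All other lists and comparisons lay between 8.14 and 92.15, and no percentile is adjusted for their number.

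Other named windows that fell in EP300-KO were those of BCL2, an inhibitor of apoptosis (48.3 ± 4.94 to 30.9 ± 0.875 kb, limma log2 difference -0.38, SE 0.06, adjusted p = 0.013), HLA-DRA (28.5 ± 0.288 to 16.8 ± 0.211 kb, -0.50, SE 0.10, adjusted p = 0.024) and CD83 (6.55 ± 1.46 to 2.20 ± 0.496 kb, -1.27, SE 0.26, adjusted p = 0.028). In all, 5 of the 24 named windows tested fell over all windows, the count was 5 when adjusted over the list alone, and none rose. None of the windows of the 5 germinal-centre transcription factors (BCL6, IRF8, POU2AF1, MEF2B, SPIB) passed, with BCL6 at -0.17 (adjusted p = 0.14) and IRF8 at -0.28 (adjusted p = 0.11). Neither did those of CD79A, CD40, CD74, MYC, PRDM1, IRF4, the edited genes, or the controls ACTB, CD3E, CD14 and ALB. Among these controls, the ALB window had -0.28 (23.8 ± 1.26 kb in WT and 16.4 ± 0.041 kb in EP300-KO, limma adjusted p = 0.14) and the CD3E window -0.16 (adjusted p = 0.10), both larger than the difference of the S1PR2 window. The TNFAIP3 window was below the filter. FOXO1 alone stayed past the threshold under each of 12 alternatives. The others lost it in 1 to 5 of these, among them without the first EP300-KO clone (adjusted p = 0.19 for CXCR4, 0.063 for BCL2, 0.13 for HLA-DRA and 0.16 for CD83). Without the second EP300-KO clone HLA-DRA (0.057) missed it, without either CREBBP-KO clone CXCR4 (0.074 and 0.072), with the 4 clones alone CXCR4 (0.076), without the first WT clone CD83 (0.058) and without the second CXCR4 (0.074).

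**Figure D4:**
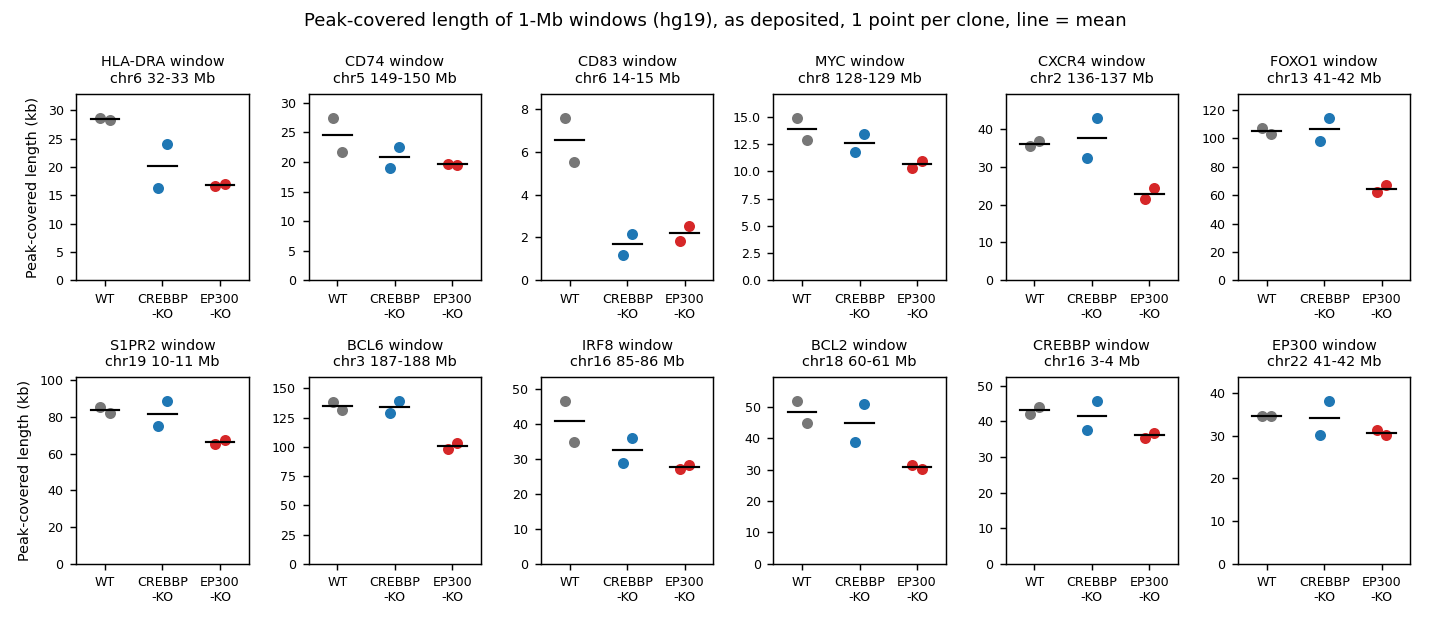
Each panel gives the peak-covered length (y axis, kb, from 0) of a 1-Mb window of hg19 in the lists as deposited, with a point per clone and a line at the mean of the 2 clones. In the FOXO1 window the EP300-KO mean is 64.3 kb against 105 kb in WT, and in the CD83 window both knock-outs lie below WT, at 1.69 and 2.20 kb against 6.55 kb.

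Over all 1971 windows, limma called 179 lower and 95 higher in EP300-KO than in WT. The median window of the EP300-KO clones lay 0.24 and 0.27 below the WT mean on the log2 scale before centring (-0.24 and -0.27), and those of the CREBBP-KO clones at -0.23 and 0.08, so these directions are relative to each clone's median. With no centring the calls were 389 lower and 34 higher, and with quantile normalization 182 and 161. The total of 274 was 54 without the first EP300-KO clone, 163 without the second, 139 without the first CREBBP-KO clone and 1 fewer without the second.

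The knock-outs were then compared directly, which asks whether the effects of losing either enzyme differ. More regions had peaks in CREBBP-KO and not in EP300-KO than the reverse. In both CREBBP-KO clones and neither EP300-KO clone were 3177 regions, the reverse held for 1364, and the crossed counts reached at most 708. Wide domains split 126 to 1 in the same direction, with crossed counts of at most 10. Absence here too means that no stitched stretch reached 10 kb covered. The domain on chromosome 4 at 114469219 to 114566061, counted as absent, held 14.5 ± 1.19 kb in EP300-KO and 29.8 ± 4.18 kb in CREBBP-KO. limma called 1432 regions higher and 378 lower in CREBBP-KO. The largest was on chromosome 4 at 108510041 to 108513572, with 3234.5 ± 251 bases in CREBBP-KO and none in EP300-KO (log2 difference 4.89, SE 0.12, adjusted p = 0.00063). In the other direction, the region on chromosome 7 at 29327788 to 29331131 had 2636.5 ± 1001 bases in EP300-KO and none in CREBBP-KO (-4.89, SE 0.47, adjusted p = 0.0082), a call that ended without either EP300-KO clone (0.19 and 0.074). The chromosome 5 region that fell in CREBBP-KO had 1573 ± 11.3 bases in EP300-KO (-4.23, SE 0.16, adjusted p = 0.0015). The windows of FOXO1 (0.54, SE 0.06, adjusted p = 0.0062), CXCR4 (0.52, SE 0.09, adjusted p = 0.014) and BCL2 (0.34, SE 0.06, adjusted p = 0.014) were higher in CREBBP-KO than in EP300-KO, and those of HLA-DRA (0.05, SE 0.10) and CD83 (-0.59, SE 0.26) did not pass. In all, 5 of 24 passed over all windows and 5 adjusted over the list alone. Among all windows 444 of 1971 passed, a similar share, so the named windows did not differ more often than others. The other 2 were ALB, a liver gene taken as a control for another tissue, higher in CREBBP-KO (0.44, SE 0.11, adjusted p = 0.038), and IRF4, a plasma cell factor, lower (-0.54, SE 0.15, adjusted p = 0.045).

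At equal list length 2606 regions were only in CREBBP-KO and 1720 only in EP300-KO. With the first CREBBP-KO clone alone, 3829 regions were only in CREBBP-KO and 2808 only in EP300-KO. With the second CREBBP-KO clone alone, these counts were 9664 and 1585, so the imbalance was mostly that of the second clone. The total of 1810 regions in that comparison was 423 without the first CREBBP-KO clone, 343 without the second and 985 without the first EP300-KO clone. Without centring the split was 1732 higher and 154 lower. Of 444 windows called, 288 were higher and 156 lower in CREBBP-KO, which became 376 and 47 without centring, 248 and 251 with quantile normalization, and 247 and 246 with the centring over filtered windows. Their number fell to 96 and 35 without the first and the second CREBBP-KO clone, and to 87 and 235 without the first and the second EP300-KO clone. The CXCR4 and BCL2 calls ended without either CREBBP-KO clone or the first EP300-KO clone (adjusted p from 0.055 to 0.087), and the BCL2 call also with quantile normalization (0.18, adjusted p = 0.077). The IRF4 and ALB calls ended without any 1 of the 4 knock-out clones (adjusted p from 0.117 to 0.23 and from 0.068 to 0.16). The IRF4 call also ended with no centring (-0.36, adjusted p = 0.41), quantile normalization (0.082) and equal list length (0.054), and the ALB call with the centring over filtered windows (0.056), quantile normalization (0.081) and equal list length (0.053).

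The lists of lost regions were then compared. Of the 1491 regions lost in CREBBP-KO, 976 (65.5%) were also lost in EP300-KO. Of the 4471 lost in EP300-KO, 1882 (42.1%) had a peak in both CREBBP-KO clones and 1613 in 1 of them. Independent lists of these sizes among the 30202 regions of both WT clones would share 221 regions. Shuffled within 30 classes of WT score and covered length, lists of the same sizes shared 672 on average (616 to 723 in 1000 draws), so much of the overlap went with WT score and covered length. Both knock-outs were compared with the same 2 WT clones, and no test here removed that dependence. The shuffled lists were added after the overlap was seen. Simulated pairs of unchanged clones each lost 991 regions on average by the same rule, against 1491 in CREBBP-KO and 4471 in EP300-KO. The simulated pairs shared 177, which is 5.45 times the 32.6 of independent lists of that size. The measured count was 4.42 times its own. Longer lists limit how large such a ratio can be, so the 2 ratios cannot be set against each other. Against shuffled lists of its own sizes, the measured 976 lay above the highest draw of 723. The count was 466 at equal list length. One window, chromosome 16 at 27 to 28 Mb, had a raised share of regions lost in both knock-outs. There 9 of 23 regions were lost in CREBBP-KO (adjusted p = 0.00041) and 15 of 23 in EP300-KO (adjusted p = 1.55e-05, exact binomial tests).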

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

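The tests with lists of equal length for the first and last pattern and the share of weaker regions were chosen after the counts were seen, as were the fit on windows and its named windows as results. In the direct comparison of the knock-outs, 1810 merged regions and 444 windows of 1 Mb differed past the threshold of limma (2039 and 640 with only the 4 knock-out clones in the fit). Among named windows, the log2 difference of CREBBP-KO over EP300-KO was 0.52 for CXCR4, 0.54 for FOXO1, 0.34 for BCL2, 0.44 for ALB and -0.54 for IRF4. These are 5 of 24 named windows tested, a share similar to the 444 of all 1971 windows. The IRF4 and ALB differences passed in 5 of 12 alternatives each, and ALB had been taken as a control of another tissue.

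The first pattern is that more regions were lost in EP300-KO (4471) than in CREBBP-KO (1491). The 2 CREBBP-KO clones were unlike in this. Taken alone against both WT clones, the first CREBBP-KO clone lost 4584 regions and the second 1726. The first and second EP300-KO clones lost 6002 and 5393. The size of the gap between the knock-outs therefore rested largely on the second CREBBP-KO clone. The tables argue against shorter lists as the whole cause, since lists of equal length gave 2262 lost regions against 888 in CREBBP-KO and crossed counts of at most 350, though the excess over regions gained shrank to 2262 against 1517. Of all lost regions, 4.97% lay in windows that lost at least 50% of theirs. This argues against loss of all copies of large segments in the 1089 windows examined, each with at least 10 WT regions. A loss of fewer copies could leave most peaks in place, so this test cannot decide it. Weak peaks missed at a lower ChIP yield and a loss of acetylation cannot be told apart, because the yield of no library is known: 95.6% of lost regions (4273) were weaker ones, and the 198 in the upper 50% of both WT lists exceeded the bound set beforehand on the crossed counts (at most 2), but a yield shared by both EP300-KO clones would leave those counts low as well. Differences between single clones also stay open beside an effect of EP300 loss, since 15 pairings of 6 clones are too few for a share under 0.05. The real pairing called 3270 regions over the 3 comparisons, and 1 pairing, the real one, reached its count. The 2 other pairings with calls (1953 and 1772) both kept the 2 EP300-KO clones together. The 12 remaining pairings called 0 regions.

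The second pattern is the lower covered length of the FOXO1 and CXCR4 windows, 2 of the 3 dark zone windows, in EP300-KO, while S1PR2 differed by -0.08 and the control ALB by -0.28, neither past the threshold. Against a like fall of all windows with as much acetylated sequence, the median of the 3, which is the value of CXCR4, lay at percentile 0.35 of random matched sets, though this list is 1 of several examined. Against shorter lists, the median log2 change was -0.42 with lists of equal length. Other genes in these windows, differences between single clones and an effect of EP300 loss stay open and were not tested apart.

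The last pattern is that more regions were lost (1491) than gained (609) in CREBBP-KO. With lists of equal length 888 were lost and 1137 gained, so unequal list lengths may account for the balance. Peaks cut from the WT lists count as absent there, so the reversal cannot be read as an excess of new peaks.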

How the results depend on the processing

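The alternatives on windows of 1 Mb and the window centring were chosen after seeing the data, as were leaving out clones for wide domains and the matched reference and the unused split of controls for the overlap of losses. Equal list length gave 888 lost and 1137 gained regions in CREBBP-KO, 2262 and 1517 in EP300-KO, 466 lost in both, 14 called regions in CREBBP-KO and a difference of -167 wide domains between EP300-KO and WT (-217.5 with the lists as deposited). The best-scoring 50% of each list gave 690 and 257, 2047 and 312, 415 lost in both, and 652 regions only in EP300-KO against 1441 only in CREBBP-KO. Joining peaks within 1 kb gave 677 and 182, 1690 and 485, 394 lost in both, and 865 against 1103. Presence at 50% coverage gave 404 gained in CREBBP-KO, 2825 lost in EP300-KO and 1767 only in CREBBP-KO. The difference in wide domains was -163 with stitching within 5 kb and -69.5 with at least 20 kb covered. Fewer regions pass each stricter rule by construction. At equal length a peak cut from a longer list counts as absent, which by itself can lower losses and raise gains. How far it did so was not tested. Called regions in CREBBP-KO against WT were 4 with a pseudocount of 1000, 3 with 10, 4 without centring, 9 with 500 bases in all 6 clones and 0 with the 4 clones alone. With 500 bases in all 6 clones, 512 were called in EP300-KO and 782 between the knock-outs. Called windows in CREBBP-KO were 7 with the centring over filtered windows, 41 without centring, 6 with quantile normalization and 11 with a pseudocount of 1000, and in EP300-KO 423 without centring and 153 with the 4 clones alone.

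Leaving out a clone gave 1726 to 7683 lost and 1085 to 3961 gained regions in CREBBP-KO, 5393 to 11680 and 1269 to 2138 in EP300-KO, 1585 to 2903 only in EP300-KO, 3829 to 9664 only in CREBBP-KO and 1070 to 6212 lost in both, higher by construction since 1 clone then decides. Called regions ranged from 0 to 211 in CREBBP-KO, 670 to 1524 in EP300-KO and 343 to 1978 between the knock-outs, and called windows from 0 to 213, 54 to 331 and 35 to 639, with the lone clone assumed to vary like the others. The wide domain difference ranged from -240.5 to -194.5 and the Jaccard difference from 0.0342 to 0.107. Of 162 values of counts and overlaps 83 stayed within the limits set. Of 144 values for named windows 109 kept their side of the threshold and direction, 31 lost it and 4 gained it, and of 168 for named regions 146 kept it and 22 lost it, with no change of sign. Not run, for lack of an annotation of the build used here, were the promoter share, the promoter and distal split, the fixed gene lists and the alternatives that need transcription start sites. No paired analysis was possible because the replicate numbers used here only name clones, and the labels tie no clone of 1 genotype to a clone of another. Depth per library is unknown and limits every count of absent peaks.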

Other observations

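The tests of regions lost or gained per window were added after the region counts were seen. Beyond the named windows, some windows lost a larger share of their regions in EP300-KO than the genome as a whole. By exact binomial tests with Benjamini-Hochberg adjustment, 36 of 1089 windows lost more of their WT regions than the genome-wide 14.8%, and crossed pairs of the same clones gave 0 such windows. They included chromosome 5 at 124 to 125 Mb, where 20 of 35 regions were lost (57.1%, Wilson 95% interval 40.9 to 72.0%, adjusted p = 5.51e-06), and chromosome 15 at 59 to 60 Mb, where 24 of 48 were (36.4 to 63.6%, adjusted p = 5.51e-06). The tests take 1 rate for all regions, although the EP300-KO loss ran from 45.6% under 250 covered bases to 0.298% over 2000. Windows rich in short regions could therefore pass without a local effect, and neighbouring regions are not independent. The crossed pairs had at most 542 lost regions, against 4471, so they could less easily reach such windows. By the same tests the share gained was raised in 2 windows in EP300-KO, with 0 in the crossed pairs. These were chromosome 21 at 37 to 38 Mb (6 of 13 regions, adjusted p = 0.0019) and chromosome 10 at 50 to 51 Mb (5 of 10, adjusted p = 0.0044). In CREBBP-KO the share gained was raised in 1, chromosome 2 at 89 to 90 Mb (15 of 49, adjusted p = 1.09e-10). This is no more than the crossed pairs gave (at most 1).

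A hypothesis drawn from the domain counts is that peaks inside wide domains of the WT clones are lost in EP300-KO more often than peaks of like length outside. The share lost was 68.0% inside and 42.3% outside for regions under 250 covered bases, 42.9% and 20.3% from 250 to 500, 16.7% and 6.38% from 500 to 1000, and 3.97% and 1.81% from 1000 to 2000. Over 2000 bases it was 0.171% inside and 0.356% outside, from 2 and 9 lost regions. The hypothesis asked for a higher share inside in all 5 classes and found it in 4, so it was not met as stated, and the class that went against it rests on few regions. In CREBBP-KO the share was higher inside in none of the 5 classes.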
